A study of Homo sapiens with 17 samples.

How the data were processed

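RNA of MCF-7 cells, an estrogen receptor-positive human breast cancer cell line, was measured on 17 Affymetrix arrays. Per the labels, cells were starved overnight in SFM, the medium of the controls, and then treated with estradiol (E2, 10 nM) or with insulin-like growth factor I (IGF-I, 100 ng/mL) for 3 hr or 24 hr. The SFM group at 3 hr holds 2 arrays and each of the other 5 groups holds 3. The values are deposited log2 expression values per probe set, made with RMA per the submitters' processing notes; the RMA software, its version and its settings are not given in the sources used here. RMA subtracts background, makes the arrays' distributions equal and sums the probes of a probe set, so a change shared by most genes would be removed before deposit. The values ran from 1.648 to 15.23 and the array medians from 5.255 to 5.34. The number of arrays limits the precision, and 25% of all values lay below 2.621, a low band in which differences are compressed.

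The labels call the replicates biological but give no shared batch, day or scan date, so p-values measure the spread between these arrays and may miss variation between experiments. The SFM and IGF-I arrays are described in the labels as reanalysed arrays of earlier records, while the E2 arrays are not. A difference in handling between the E2 arrays and the rest therefore cannot be told apart from the E2 effect.

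Of the 22277 probe sets, 19070 had 1 gene symbol in the annotation used here, 1043 had several and 2164 had none, 62 of which were control probe sets. The gene identifiers of 19058 probe sets matched the current gene table, and that match changed 0 symbols. Each gene was represented by the probe set with the highest mean over the 17 arrays among those with 1 symbol, which gave 11963 genes, 4310 of them with more than 1 probe set. Among 138 named gene results that passed the test and had other probe sets, all other probe sets had the same sign in 118 and at least 1 had the opposite sign in 20. ESR1, IL1R1, N4BP2L1, MICAL2, KMO, NOP16, ERBB3, IGFBP5, INSR, TYMS and BCL2 are genes of that second kind.

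Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), tables were read with version 1.17.8 of data.table, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. All 17 arrays entered 1 fit of 6 group means without covariates, so every comparison shared the spread of all groups (11 residual and 1.51 prior degrees of freedom). The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the 11963 genes. Each agent was compared with SFM at each time, E2 with IGF-I at each time, SFM at 24 hr with SFM at 3 hr, and each agent's effect at 24 hr with its effect at 3 hr by the interaction contrast. A mean ± SD is over the arrays of a group, and a log2 fold change is given with its standard error (SE) from the fit.

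The 19 gene lists, the comparisons, the test, the alternatives and the rule for named genes were fixed before the data were examined. The lists were estrogen-induced genes, estrogen-lowered genes, immediate early genes with ERK feedback genes, FOXO target genes, the IGF axis, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, cytosolic ribosomal proteins, sterol synthesis and uptake, fatty acid synthesis, the amino acid response (ATF4 targets), endoplasmic reticulum chaperones, glycolysis and hypoxia, cell cycle brakes, apoptosis regulators, luminal identity and junctions, interferon-stimulated genes, and basal, mesenchymal, endothelial and blood cell markers. Some members were not measured as single genes, among them AREG and RBBP8 (estrogen-induced), HMGCR and LDLR (sterol synthesis) and 9 of the 25 cytosolic ribosomal proteins. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists of a comparison, and again with an estimated correlation. Every adjusted p of a list is from camera and every adjusted p of a gene is from limma's moderated test. Some genes were in more than 1 list; the FOXO list shared 12 of its members with others.

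Named genes were, for each agent and time, the 8 largest rises and 8 largest falls among genes past the threshold whose treated arrays all lay on 1 side of every control array. Of genes without any effect, 10% would show such separation by chance with 3 arrays against 3 and 20% with 3 against the 2 controls of 3 hr. From each list up to 4 members with the smallest adjusted p were added. GREB1, PGR, TFF1, CXCL12, MYC, CCND1, IRS2, IGF1R, ESR1, ERBB2 and BLNK were given at both times for both agents. For E2 against IGF-I, for change over time and for SFM over time the 5 largest differences each way were named, and for both agents together the 5 each way with the largest smaller fold.

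Simulated data had 200 of 11963 genes changed and a pooled spread per gene. Rates at each group's own spread may differ. Of 2-fold changes the fit recovered 76.1% and 80.6% (E2 and IGF-I, 3 hr) and 89.6% and 86.6% (both, 24 hr). It recovered 91% and 89.6% (E2 against IGF-I, 3 and 24 hr) and 80.6% (SFM over time). Of 1.5-fold changes it recovered only 53.7% (IGF-I at 3 hr) to 68.7% (E2 against IGF-I at 3 hr). For the IGF-I effect over time 93.5% of 4-fold changes were recovered. False calls were 2.48% (SFM over time) to 7.98% (E2 against IGF-I, 3 hr) of calls. In 20 draws of independent genes (IGF-I, 24 hr), camera called a list of 30 shifted by 0.5 in all 20. It called 2 of 333 unshifted lists, but correlated lists were not tested.

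Because both agents were compared with the same SFM arrays, overlaps of their calls were set beside 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. Replicate numbers were checked for pairing by the correlation of same-numbered arrays' deviations from their group means. For E2 and IGF-I at 3 hr the 3 correlations were 0.561, 0.26 and 0.49, so the numbers pair those arrays, although no label says what they shared. Signs of RNA quality were checked as the 3' minus 5' signal of the ACTB and GAPDH control probe sets. No difference between groups passed a two-sided exact permutation test (lowest p = 0.2, ACTB for E2 against SFM at 24 hr, a difference of −0.345), but 3 arrays against 3 cannot give a p below 0.1. Correlations between arrays of a group ran from 0.9898 to 0.9979 and no 2 arrays were identical.

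Alternatives were quantile normalization again, centring each array on its median, leaving out the dimmer 50% of genes, the mean of a gene's probe sets, every probe set on its own, a gene's next probe set, array weights, a trended robust prior, only the arrays of the groups compared, a minimum fold of 1.5, the replicate number as a block, and leaving out each array in turn. Leaving out 1 SFM array at 3 hr leaves a single array there, which is assumed to vary like the other groups. Alternatives chosen after seeing the data were leaving out E2 24 hr replicate 3 from every comparison, the ACTB signal as a covariate, and the replicate block with the 3 hr arrays alone. Probe sets without a single gene name were left out of the gene tests and tested separately.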

Results

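Gene expression was measured in MCF-7 cells that had been starved overnight in SFM and then kept in SFM, treated with 10 nM estradiol (E2) or treated with 100 ng/mL IGF-I. Cells were taken after 3 hr and after 24 hr, which gave 6 groups of 3 arrays, except for SFM at 3 hr with 2. Estradiol acts on MCF-7 cells through the estrogen receptor, and IGF-I, a growth factor related to insulin, through a receptor tyrosine kinase. The design asks which genes each hormone changes early and late, and how far the changes are shared. After 3 hr, 152 of 11963 genes passed the test with E2 (83 higher, 69 lower) and 1940 with IGF-I (953 higher, 987 lower). After 24 hr the counts were 665 with E2 (300 higher, 365 lower) and 2542 with IGF-I (1214 higher, 1328 lower). Arrays of the same group correlated at 0.9898 or higher.

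After 3 hr of E2, known estrogen-induced genes rose and known estrogen-lowered genes fell. PLAC1, a gene of the placenta, rose 8.86-fold, from 3.83 ± 0.41 (SD, n = 2) to 6.98 ± 0.18 (SD, n = 3). EGR3, an immediate early transcription factor, rose 3.93-fold (log2 1.97 ± 0.11, SE). PGR, the progesterone receptor, rose from 7.29 ± 0.02 (SD, n = 2) to 8.41 ± 0.12 (SD, n = 3). MME, the membrane peptidase neprilysin, fell 5.23-fold (log2 −2.39 ± 0.28, SE). ERBB4, a receptor of the EGF receptor family, fell by 1.76 ± 0.23 (SE) on the log2 scale. The adjusted p-values were 0.000702 for PLAC1, 2.16e-06 for EGR3, 0.00134 for PGR, 0.000938 for MME and 0.00215 for ERBB4. All 3 treated arrays lay on 1 side of both controls.

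The 8 largest rises with E2 at 3 hr were PLAC1, IL17RB, PDLIM3, EGR3, OLFML3, ABHD2, CYP26B1 and MICAL2, with log2 fold changes of 1.71 to 3.15. The 8 largest falls were MME, IL1R1, HCAR3, TNFRSF11B, PALMD, KMO, ERBB4 and ELF5, with log2 fold changes of −2.39 to −1.57. PALMD lay in the low band of the scale, and the next probe set of IL1R1 showed no fall (0.000296). Without SFM replicate 1 the calls of ABHD2, CYP26B1, TNFRSF11B and KMO were lost, and without SFM replicate 2 those of OLFML3, CYP26B1 and PALMD. Their highest adjusted p-values were between 0.0544 (ABHD2) and 0.111 (PALMD). In all, 16 of the 34 named genes called here kept their call with each of the 5 arrays left out in turn. The count fell from 152 to 83 without SFM replicate 1 (25 higher, 58 lower) and to 100 without SFM replicate 2 (40 higher, 60 lower), so the majority of rises turned to a majority of falls.

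Of 26 estrogen-induced genes, 6 rose and 0 fell with E2 at 3 hr, and 16 rose when adjusted over the list alone (median log2 0.77, camera adjusted p = 3.59e-25). In the fit without E2 24 hr replicate 3, 12 rose. Among them were PGR, CXCL12, a chemokine (1.30 ± 0.25, SE, adjusted p = 0.0225), and MYBL1, a transcription factor (1.64 ± 0.17, SE, adjusted p = 0.000425). CXCL12 lost its call without either SFM array and without E2 replicate 1 or 2 (adjusted p up to 0.16). GREB1, an estrogen receptor cofactor, had a log2 difference of 0.86 ± 0.20 (SE, adjusted p = 0.0657). TFF1, a secreted estrogen-responsive peptide, was near the top of the scale in both groups, at 14.64 with E2 and 14.52 with SFM (adjusted p = 0.339). MYC (0.45, adjusted p = 0.538), CCND1, the gene of cyclin D1 (0.22, adjusted p = 1), IRS2 (0.26, adjusted p = 0.582), IGF1R (0.80, adjusted p = 0.718) and ERBB2 (−0.74, adjusted p = 0.139) did not pass. ESR1, the estrogen receptor itself, fell by 0.42 ± 0.07 (SE, adjusted p = 0.0116), and 7 of its 8 other probe sets also had lower means. ESR1 and BLNK, an adaptor protein (−1.32 ± 0.22, SE, adjusted p = 0.00984), lost their calls without either SFM array (adjusted p up to 0.113 and 0.0853).

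Of 12 estrogen-lowered genes, 5 fell and 0 rose with E2 at 3 hr (adjusted over the list alone, 9 fell and 1 rose; median −0.56, adjusted p = 9.04e-13). EFNA1, an ephrin ligand, fell by 0.98 ± 0.13 (SE) and BIK, a proapoptotic gene, by 1.01 ± 0.15 (SE); the other falls were BLNK, ESR1 and IL1R1. Of 19 ribosome biogenesis genes, 3 rose (DDX21, NOLC1 and NOP16) and 9 rose when adjusted over the list alone (median 0.41, adjusted p = 4.17e-14). Each of these 3 lost its call without SFM replicate 1 or without SFM replicate 2 (adjusted p up to 0.189). DDX21 lost it also without E2 replicate 3 and NOP16 also without E2 replicate 1 or 2. Of 34 genes of G1/S and DNA replication, MCM10, a replication factor, rose (0.67 ± 0.09, SE, adjusted p = 0.00258). Adjusted over the list alone 11 rose (median 0.24, list adjusted p = 5.31e-11). These 4 list calls held with an estimated correlation, with adjusted p-values of 0.000121 (both estrogen lists), 0.0012 (ribosome biogenesis) and 0.00483 (G1/S).

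Further lists were called with E2 at 3 hr only under the preset correlation. Immediate early genes had 1 rise, EGR3, and 1 fall, IER3 (−1.35 ± 0.16, SE), among 22 (adjusted over the list alone 4 and 1; median 0.12, adjusted p = 0.0371; adjusted p = 0.233 with an estimated correlation). The FOXO list had 0 rises and 0 falls among 23 (adjusted over the list alone 0 and 1; median −0.16, adjusted p = 0.0358; adjusted p = 0.233 with an estimated correlation). G2/M genes had a median of −0.11 with 0 of 30 called, also when adjusted over the list alone (adjusted p = 0.0199; adjusted p = 0.497 with an estimated correlation). Sterol genes (median 0.12, adjusted p = 0.0371), endoplasmic reticulum chaperones (0.18, adjusted p = 0.0236) and cell cycle brakes (−0.12, adjusted p = 0.0431) had 0 called members, and adjusted p-values of 0.103, 0.202 and 0.131 with an estimated correlation. Adjusted over the list alone, 1 sterol gene rose, 0 chaperones changed, and 1 brake rose and 1 fell. Each of these 6 calls was also lost when single arrays were left out (adjusted p up to 0.201). This was so without SFM replicate 2 (all but G2/M), without E2 replicate 1 (all 6), without E2 replicate 2 (immediate early and FOXO genes) and without SFM replicate 1 (sterol genes). Without the dimmer 50% of genes all but G2/M were lost as well (up to 0.279).

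After 24 hr of E2, MME was the most strongly lowered gene, and genes of the cell division machinery were higher. MME was at 2.73 ± 0.50 with E2 and at 8.39 ± 0.03 with SFM (SD, n = 3; adjusted p = 1.52e-07). The E2 level lies near the low band, where differences are compressed, so the size of this fall is uncertain. PLAC1 was 10.1-fold higher (log2 3.33 ± 0.31, SE, adjusted p = 7.32e-05) and MYBL1 7.08-fold higher (9.21 ± 0.24 against 6.38 ± 0.23, SD, n = 3; adjusted p = 7.87e-07). PGR rose by 1.42 ± 0.12 (SE, adjusted p = 4.22e-05) and CXCL12 by 1.45 ± 0.22 (SE, adjusted p = 0.00216). IL1R1, the interleukin-1 receptor, fell 8.18-fold (log2 −3.03 ± 0.27, SE, adjusted p = 5.74e-05). Each of these genes was separated on all 6 arrays.

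The 8 largest rises with E2 at 24 hr were PLAC1, MYBL1, UGT2B15, CCN5, SYBU, MGP, MMP10 and PDLIM3 (log2 1.91 to 3.33). The 8 largest falls were MME, IL1R1, FBN2, TSPAN12, NELL2, SASH1, SLC24A3 and BLNK (−5.66 to −1.94). The call of CCN5 was lost without any single SFM array or without E2 replicate 3 (adjusted p up to 0.108). The call of SASH1 was lost without SFM replicate 2, SFM replicate 3 or E2 replicate 3 (up to 0.0734), and that of SLC24A3 without SFM replicate 1 (0.0511). ESR1 was lower by 0.61 ± 0.06 (SE, adjusted p = 0.00018) on its brightest probe set, but 6 of its 8 other probe sets had higher means with E2. GREB1 (0.55, adjusted p = 0.107), TFF1 (0.04, adjusted p = 0.681), MYC (0.06, adjusted p = 0.916), CCND1 (−0.12, adjusted p = 0.818), IRS2 (0.01, adjusted p = 0.98), IGF1R (0.42, adjusted p = 0.671) and ERBB2 (−0.50, adjusted p = 0.168) did not pass. Of 57 named genes called, 41 kept their call with each array left out in turn. The count fell from 665 to 395 without SFM replicate 2, to 407 without SFM replicate 3 and to 84 with only the 2 groups in the fit. Without E2 replicate 2 rises were the majority (326 higher, 305 lower).

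All 30 genes of G2/M and mitosis had higher means with E2 at 24 hr, of which 25 passed the test (30 adjusted over the list alone; median 0.85, adjusted p = 2.19e-36). Without E2 replicate 3, which stood apart in this list too (mean 9.25 against 8.82 and 8.83), 18 rose (median 0.69). PRC1, a protein of the central spindle, rose by 1.01 ± 0.11 (SE) and KIF20A, a mitotic kinesin, by 0.99 ± 0.13 (SE). CDCA8 rose by 1.13 ± 0.13 (SE) and CDK1, the mitotic kinase, by 0.80 ± 0.11 (SE). Of 34 genes of G1/S and DNA replication, 15 rose and 0 fell (24 adjusted over the list alone; median 0.53, adjusted p = 1.77e-24). Among them were MCM10 (1.16 ± 0.08, SE), RRM2, a subunit of ribonucleotide reductase (1.14 ± 0.09, SE), and CDC45, a replication factor (1.21 ± 0.14, SE). The 2 lists had adjusted p-values of 0.00444 and 0.000278 with an estimated correlation. The next probe set of TYMS, thymidylate synthase, had a difference of −0.10 where the brighter one rose by 0.86.

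Of the 26 estrogen-induced genes, 10 rose and 0 fell with E2 at 24 hr (13 and 1 over the list alone; median 0.55, adjusted p = 1.94e-12). Of the 12 estrogen-lowered genes 8 fell (10 fell and 1 rose over the list alone; median −0.67, adjusted p = 4.67e-11). EGR3 (1.13 ± 0.10, SE) rose, while EFNA1 (−1.27 ± 0.12, SE) and BIK (−1.12 ± 0.13, SE) fell. FOXO target genes had 8 falls and 0 rises among 23 (10 falls over the list alone; median −0.37, adjusted p = 4.86e-05), and 5 falls without E2 replicate 3. CCNG2, a cyclin of resting cells (−0.74 ± 0.11, SE), and RBL2, a retinoblastoma family member (−0.68 ± 0.13, SE), were among the falls. Cell cycle brakes had 3 falls and 0 rises among 18 (5 falls and 1 rise over the list alone; median −0.34, adjusted p = 0.00193). Of 14 sterol genes 3 rose, DHCR7, INSIG1 and MSMO1 (6 over the list alone; median 0.33, adjusted p = 1.35e-05). INSIG1 lost its call without SFM replicate 1 or E2 replicate 3 (adjusted p up to 0.0591), and MSMO1 without any array but E2 replicate 2 (up to 0.134). Using an estimated correlation, adjusted p-values were 0.00214 (estrogen-induced and sterol), 0.000278 (estrogen-lowered), 0.0381 (FOXO) and 0.0201 (brakes).

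Amino acid response genes had a median of 0.44 with E2 at 24 hr, with 1 rise, SLC7A5, among 24, also over the list alone (adjusted p = 6.37e-05; adjusted p = 0.403 with an estimated correlation). This rested on E2 replicate 3, in which the list lay 1.32 above the mean of replicates 1 and 2. Without that array the median was 0.05 (adjusted p = 0.829), and SLC7A5, an amino acid transporter, lost its call. SLC7A5 lost it also without SFM replicate 2, SFM replicate 3 or E2 replicate 2 (adjusted p up to 0.104). Endoplasmic reticulum chaperones had 1 rise, CRELD2, among 18, also over the list alone (median 0.12, adjusted p = 0.0455; adjusted p = 0.248 with an estimated correlation). Without E2 replicate 3 their adjusted p was 0.539. That call was also lost without SFM replicate 1 or 2. Fatty acid synthesis genes had 1 rise, SCD, a fatty acid desaturase (0.97 ± 0.15, SE), among 9 (2 over the list alone; median 0.10, adjusted p = 0.0319; adjusted p = 0.104 with an estimated correlation). Their call was lost without SFM replicate 1 or E2 replicate 2 (up to 0.0749), and their median was 0.20 without E2 replicate 1. The fatty acid and chaperone calls were also lost with quantile normalization again (adjusted p = 0.0504 and 0.0967) and without the dimmer 50% of genes (both 0.116). Luminal identity genes had 3 falls among 22 (8 falls and 1 rise over the list alone; median −0.28, adjusted p = 0.000129; adjusted p = 0.0641 with an estimated correlation).

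After 3 hr of IGF-I, genes of sterol synthesis, ribosome biogenesis and DNA replication rose, and genes known to be switched on by FOXO factors in starved cells fell. EGR3 rose 5.53-fold, from 7.11 ± 0.08 (SD, n = 2) to 9.58 ± 0.10 (SD, n = 3; adjusted p = 9.62e-08). STON1, an adaptor of endocytosis, fell 16-fold (log2 −4.00 ± 0.46, SE, adjusted p = 9.08e-05). HBP1, a transcriptional repressor of cell cycle genes, fell 6.55-fold (log2 −2.71 ± 0.12, SE, adjusted p = 9.22e-08). IRS2, an adaptor of the insulin and IGF-I receptors, fell 4.14-fold, from 8.98 ± 0.05 (SD, n = 2) to 6.93 ± 0.18 (SD, n = 3; adjusted p = 9.55e-07). PGR fell with IGF-I, from 7.29 ± 0.02 (SD, n = 2) to 5.92 ± 0.15 (SD, n = 3; adjusted p = 3.77e-05), in all 3 arrays.

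The 8 largest rises with IGF-I at 3 hr were EGR3, PHLDA2, GAL, TUBB2A, SLC7A11, FHL2, MVD and P2RY2 (log2 2.14 to 2.47). The 8 largest falls were STON1, TSPAN12, KCNJ8, HBP1, N4BP2L1, BLNK, CCDC28A and SELENOP (−4.00 to −2.25). SLC7A11, the cystine transporter, and SELENOP, a selenium carrier, lost their calls without any 1 of the 5 arrays (adjusted p up to 0.225 and 0.147). GREB1 fell by 0.78 ± 0.20 (SE, adjusted p = 0.0182), a call lost without SFM replicate 2, IGF-I replicate 1 or IGF-I replicate 2 (up to 0.159). MYC fell by 0.66 ± 0.21 (SE, adjusted p = 0.0475), which was lost without any array but IGF-I replicate 1 (up to 0.392). ERBB2 fell by 0.66 ± 0.21 (SE, adjusted p = 0.0465), lost without any array but IGF-I replicate 2 (up to 0.188). With the replicate number as a block MYC and ERBB2 also missed the threshold. ESR1 fell by 0.47 ± 0.07 (SE, adjusted p = 0.000747), as did 6 of its 8 other probe sets. CCND1 (0.46, adjusted p = 0.213), IGF1R (−0.35, adjusted p = 0.801), TFF1 (0.04, adjusted p = 0.711) and CXCL12 (−0.04, adjusted p = 1) did not pass. Of 86 named genes called, 71 kept their call with each array left out in turn. The count of 1940 became 1147 without SFM replicate 1 and 1111 without SFM replicate 2.

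Of 23 FOXO target genes, 15 fell and 0 rose with IGF-I at 3 hr (16 fell over the list alone; median −1.02, adjusted p = 3.31e-12). Falls in this list were IRS2, PIK3IP1, an inhibitor of PI3 kinase (−2.03 ± 0.18, SE), CITED2, a transcriptional coregulator (−2.21 ± 0.17, SE), and TXNIP, an inhibitor of glucose uptake (−1.60 ± 0.11, SE). Of 22 immediate early and ERK feedback genes, 9 rose and 3 fell (10 and 3 over the list alone; median 0.41, adjusted p = 0.00012). DUSP6, an ERK phosphatase (1.30 ± 0.23, SE), and ETV5, an ETS factor (1.62 ± 0.27, SE), were among the rises. Cell cycle brakes had 7 falls and 0 rises among 18 (8 falls and 1 rise over the list alone; median −0.35, adjusted p = 0.000119). The falls included CCNG2 (−1.38 ± 0.12, SE), RBL2 (−1.48 ± 0.15, SE) and BTG1 (−1.47 ± 0.21, SE). Estrogen-lowered genes also fell with IGF-I, 10 of 12, the same count over the list alone (6 of the members are also in other lists; median −1.15, adjusted p = 9.08e-11). Adjusted p-values with an estimated correlation were 0.0019 (FOXO), 0.0283 (immediate early), 0.00491 (brakes) and 0.000204 (estrogen-lowered). The call of immediate early genes was lost without the dimmer 50% of genes (adjusted p = 0.0569).

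Sterol synthesis genes rose with IGF-I at 3 hr in 12 of 14 cases, the same count over the list alone (median 1.13, adjusted p = 3.31e-12). MVD (2.16 ± 0.23, SE), HMGCS1 (2.02 ± 0.23, SE), MSMO1 (1.51 ± 0.09, SE) and FDPS (1.31 ± 0.15, SE), all enzymes of the pathway, were among them. Of 9 fatty acid synthesis genes 6 rose (8 over the list alone; median 0.92, adjusted p = 1.29e-06). Of 19 ribosome biogenesis genes 14 rose (15 over the list alone; median 0.98, adjusted p = 3.09e-13), including DDX21 (1.56 ± 0.14, SE) and NOP16 (1.46 ± 0.12, SE). Of 34 genes of G1/S and DNA replication, 24 rose and 0 fell (28 over the list alone; median 0.69, adjusted p = 3.36e-18), with MCM10 (1.76 ± 0.09, SE) and CDC6, a replication licensing factor (1.82 ± 0.20, SE). Cytosolic ribosomal proteins had small differences, with 2 falls among 16, RPS9 and RPL11 (3 over the list alone; median −0.10, adjusted p = 0.00307). RPL11 lost its call without any array but IGF-I replicate 1 (adjusted p up to 0.129), and the list lost its call without the dimmer 50% of genes (adjusted p = 0.0724). When the correlation was estimated, adjusted p-values were 0.000192 (sterol), 0.00213 (fatty acid), 0.00118 (ribosome biogenesis), 0.000664 (G1/S) and 0.0188 (ribosomal proteins).

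Some list calls for IGF-I at 3 hr did not hold with an estimated correlation. Mitotic genes had 12 falls and 1 rise among 30 (13 and 1 over the list alone; median −0.38, adjusted p = 1.64e-05; adjusted p = 0.23 with an estimated correlation). KIF20A (−1.10 ± 0.14, SE) and HMMR (−1.05 ± 0.20, SE) were among the falls. Amino acid response genes had 7 rises and 0 falls among 24 (10 rises over the list alone; median 0.78, adjusted p = 3.32e-06; adjusted p = 0.247 with an estimated correlation), including SLC7A5 (1.59 ± 0.30, SE). Post hoc, without E2 24 hr replicate 3, 18 of them rose and the list passed with an estimated correlation (adjusted p = 0.000264). Glycolysis genes had 8 rises and 2 falls among 21, the same over the list alone (median 0.37, adjusted p = 0.00307; adjusted p = 0.0553 with an estimated correlation). PFKFB3, an activator of glycolysis (0.92 ± 0.15, SE), and LDHA (0.62 ± 0.07, SE), were among the rises. Genes of the IGF axis had 5 falls among 16 (median −0.24, adjusted p = 0.00542; adjusted p = 0.126 with an estimated correlation), among them IRS2 and IRS1 (−0.70 ± 0.12, SE). Their median was −0.15 without IGF-I replicate 1 and −0.39 without IGF-I replicate 2, and that of glycolysis genes was 0.22 without SFM replicate 2. Luminal identity genes had 5 falls and 1 rise among 22 (median −0.28, adjusted p = 0.0104; adjusted p = 0.19 with an estimated correlation). Among these falls was ERBB3, a receptor of the EGF receptor family (−1.51 ± 0.22, SE), while its far dimmer next probe set had a difference of 0.07. The counts of the IGF axis and luminal lists were the same when adjusted over the list alone. Glycolysis, IGF axis and luminal genes lost their calls without the dimmer 50% of genes (adjusted p = 0.0569, 0.0622 and 0.0569).

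After 24 hr of IGF-I, mitotic genes and lipid synthesis genes were higher, and many genes lowered at 3 hr were also lower. SLC7A11 rose 8.54-fold, from 5.34 ± 0.28 to 8.43 ± 0.28 (SD, n = 3; adjusted p = 0.00497). ASNS, asparagine synthetase, rose 4.67-fold, from 10.01 ± 0.07 to 12.23 ± 0.07 (SD, n = 3; adjusted p = 0.00414), and SCD 3.82-fold (log2 1.93 ± 0.15, SE, adjusted p = 5.16e-06). N4BP2L1 fell 9.81-fold (log2 −3.29 ± 0.24, SE, adjusted p = 2.56e-06), with 3 of its 5 other probe sets lower too. MME fell 6.57-fold (log2 −2.71 ± 0.25, SE, adjusted p = 1.4e-05) and IRS2 3.01-fold (log2 −1.59 ± 0.11, SE, adjusted p = 2.43e-06). All 3 treated arrays lay beyond all 3 controls for each.

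The 8 largest rises with IGF-I at 24 hr were SLC7A11, CHAC1, CA4, CLGN, FILIP1L, RASSF1, NIBAN1 and ASNS (log2 2.22 to 3.09). The 8 largest falls were N4BP2L1, SELENOP, STON1, CAV1, TSPAN12, MME, IL1R1 and PTGER4 (−3.29 to −2.65). MYC fell by 0.67 ± 0.19 (SE, adjusted p = 0.0215), a call lost without SFM replicate 1, IGF-I replicate 1 or IGF-I replicate 3 (adjusted p up to 0.0859). ESR1 was lower by 0.56 ± 0.06 (SE, adjusted p = 7.95e-05), with 4 of its 8 other probe sets lower, and BLNK by 1.78 ± 0.20 (SE). PGR (0.12, adjusted p = 0.521), GREB1 (−0.46, adjusted p = 0.0925), CXCL12 (0.29, adjusted p = 0.401), TFF1 (0.06, adjusted p = 0.257), IGF1R (0.07, adjusted p = 0.923), CCND1 (−0.18, adjusted p = 0.564) and ERBB2 (−0.19, adjusted p = 0.518) did not pass. Of 89 named genes called, 82 kept their call with each of the 6 arrays left out in turn (1917 to 2247 calls).

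All 30 mitotic genes rose with IGF-I at 24 hr, also over the list alone (median 1.26, adjusted p = 3.7e-31). Among them were PRC1 (1.81 ± 0.11, SE), CDCA8 (1.71 ± 0.13, SE), CCNB1, cyclin B1 (1.23 ± 0.10, SE), and BUB1B, a spindle checkpoint kinase (log2 1.19). Of 34 G1/S and replication genes 24 rose and 0 fell (27 over the list alone; median 0.79, adjusted p = 1.5e-17), with CDC45 (2.0 ± 0.14, SE) and MCM10 (1.86 ± 0.08, SE). Fatty acid synthesis genes had 6 rises among 9 (7 over the list alone; median 0.58, adjusted p = 7.5e-06), including SREBF1, their transcriptional regulator (1.44 ± 0.21, SE). Sterol genes had 5 rises and 1 fall among 14 (7 and 1 over the list alone; median 0.32, adjusted p = 0.00219), with FDPS (1.11 ± 0.13, SE). Cytosolic ribosomal proteins had 5 falls among 16 (7 over the list alone; median −0.19, adjusted p = 0.00978), the largest being RPS15 among those named (−0.26 ± 0.05, SE). Estrogen-lowered genes had 7 falls and 1 rise among 12 (7 and 2 over the list alone; median −0.67, adjusted p = 0.000527). Estimating the correlation gave adjusted p-values of 0.0105 (mitotic and estrogen-lowered), 0.00251 (G1/S), 0.00953 (fatty acid), 0.0181 (sterol) and 0.0412 (ribosomal proteins). With E2 24 hr replicate 3 left out of the fit, the ribosomal proteins had adjusted p = 0.0601 with an estimated correlation. Without the dimmer 50% of genes the sterol and ribosomal protein calls were lost (adjusted p = 0.127 and 0.0623).

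Amino acid response genes had 20 rises and 0 falls among 24 with IGF-I at 24 hr (21 over the list alone; median 1.45, adjusted p = 6.23e-14; adjusted p = 0.095 with an estimated correlation). CEBPG, a transcription factor (2.16 ± 0.27, SE), SLC7A5 (2.16 ± 0.27, SE) and AARS1, a transfer RNA synthetase (1.43 ± 0.19, SE), were among them. Post hoc, without E2 24 hr replicate 3, 21 rose and the list passed with an estimated correlation (adjusted p = 6.13e-05). ATF3, a stress-induced factor of the immediate early list, also rose (2.0 ± 0.38, SE). FOXO target genes had 11 falls and 2 rises among 23 (12 and 2 over the list alone; median −0.70, adjusted p = 0.000396; adjusted p = 0.0616 with an estimated correlation). IRS2 and INSR, the insulin receptor (−1.87 ± 0.28, SE), were among the falls. Immediate early genes had 9 rises and 3 falls among 22 (11 and 3 over the list alone; median 0.37, adjusted p = 0.00127; adjusted p = 0.0616 with an estimated correlation, and 0.0202 without E2 24 hr replicate 3 in the fit), including DUSP6 (1.42 ± 0.21, SE). Glycolysis genes had 9 rises and 3 falls among 21 (10 and 4 over the list alone; median 0.21, adjusted p = 0.0123; adjusted p = 0.095 with an estimated correlation), and their median was 0.52 without IGF-I replicate 1 and 0.08 without IGF-I replicate 2. Luminal identity genes had 7 falls and 2 rises among 22 (8 and 2 over the list alone; median −0.29, adjusted p = 0.0351; adjusted p = 0.268 with an estimated correlation). They lost their call without SFM replicate 1 or IGF-I replicate 1 (up to 0.106). Without the dimmer 50% of genes the immediate early, glycolysis and luminal calls were lost (adjusted p = 0.146, 0.298 and 0.0512), the last 2 also with the mean of a gene's probe sets (0.0545 and 0.109).

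**Figure D1:**
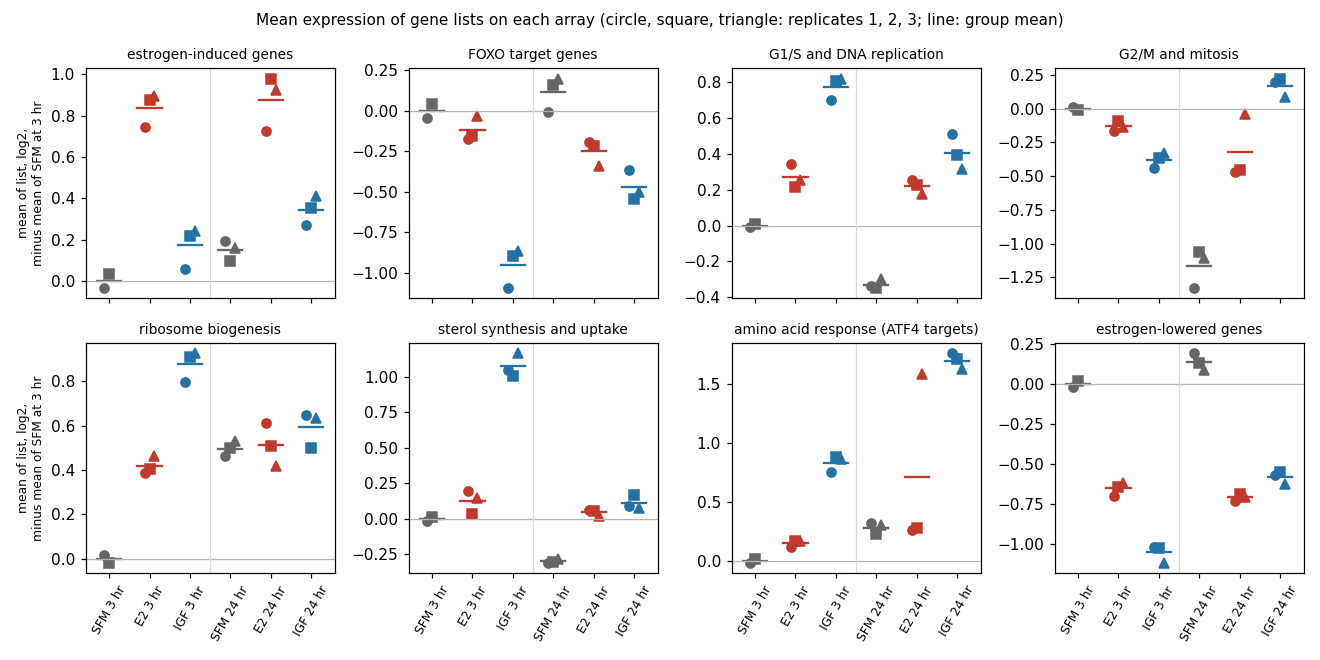
Mean log2 expression of 8 gene lists on each array minus the mean of the SFM arrays at 3 hr (vertical axes, log2) for the 6 groups (horizontal axes); circles, squares and triangles are replicates 1, 2 and 3 and lines are group means. Estrogen-induced genes lie 0.745 to 0.895 above the reference on the E2 arrays at 3 hr, mitotic genes lie at −1.33 to −1.06 on the SFM arrays at 24 hr, and amino acid response genes lie at 1.59 on E2 24 hr replicate 3 against 0.261 and 0.277 on replicates 1 and 2.

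Many genes were called with both agents in the same direction. At 3 hr 32 genes rose and 56 fell with both, where independent lists would share 6.61 and 5.69. Unchanged groups against the same controls shared 0.03 on average over 100 simulations (at most 1). PLAC1, EGR3, MICAL2, METTL1 and HOMER2 led the shared rises, and IL1R1, ELF5, an ETS factor of luminal progenitors, ERBB4, KMO and PALMD the shared falls. The shared falls were 81.2% of the genes that fell with E2, and the shared rises 38.6% of those that rose. The covariance of the 2 sets of log2 fold changes across genes, which are not independent replicates, was 0.0563 (r = 0.494), against 0.0218 (r = 0.599) in the simulations, a difference of 0.0345. Without E2 replicate 1 the number shared in 1 direction was 57 instead of 88. Without SFM replicate 1 only 8 rises but 55 falls were shared, and without SFM replicate 2, 18 rises and 56 falls. METTL1 and HOMER2 lost their E2 call, each without SFM replicate 1, E2 replicate 1 or E2 replicate 3 (adjusted p up to 0.389). METTL1 lost it also without SFM replicate 2 and HOMER2 also without E2 replicate 2.

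At 24 hr 213 genes rose and 255 fell with both agents, where independent lists would share 30.4 and 40.5. The simulations without effects shared 0, again by construction. PLAC1 (3.33 with E2, 1.52 with IGF-I), MYBL1 (2.82 and 2.21), EXO1 (1.46 and 1.61), NRGN (1.40 and 1.89) and MNS1 (1.37 and 1.43) were the leading shared rises. MME (−5.66 and −2.71), IL1R1 (−3.03 and −2.71), TSPAN12 (−2.33 and −2.82), PDE8B, a cyclic AMP phosphodiesterase (−1.85 and −2.04), and ATP8A1 (−1.82 and −2.02), were the leading shared falls. The covariance across genes was 0.0926 (r = 0.634) against 0.0146 (r = 0.501) in the simulations, a difference of 0.078. The controls are too few to be split, so part of the excess at either time may come from the shared controls. At 3 hr the simulations also left out that same-numbered E2 and IGF-I arrays deviate together, which may add to the covariance. Without SFM replicate 2 or 3 the 468 genes shared in 1 direction became 288 and 307. MNS1 lost its E2 call without SFM replicate 1, SFM replicate 3 or E2 replicate 3 (adjusted p up to 0.125).

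**Figure D2:**
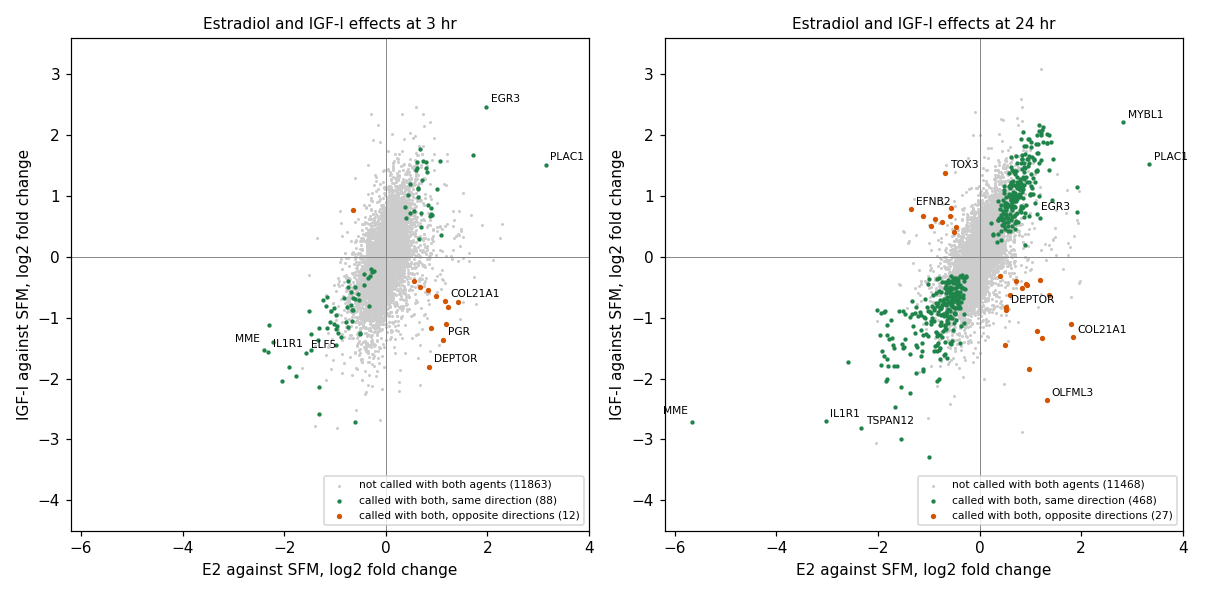
Log2 fold change of each gene with E2 (horizontal axes) against that with IGF-I (vertical axes), each relative to SFM, at 3 hr and at 24 hr; grey points are genes not called with both agents, green points genes called with both in the same direction and orange points genes called with both in opposite directions. At 3 hr 88 genes are green and 12 orange, and at 24 hr 468 are green and 27 orange, with MME farthest to the left.

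Compared directly at 3 hr, 1657 genes differed between E2 and IGF-I (845 higher with E2, 812 lower). DEPTOR, an inhibitor of mTOR, was higher with E2 by 2.67 ± 0.09 (SE, adjusted p = 7.12e-09), as were STON1 (3.11 ± 0.41, SE), LOC100996756 (2.78 ± 0.29, SE), N4BP2L1 (2.58 ± 0.24, SE) and ABHD2 (2.55 ± 0.23, SE). GAL, the neuropeptide galanin (−2.65 ± 0.34, SE), MVD (−2.31 ± 0.20, SE), CORO1A (−2.17 ± 0.26, SE), TUBB2A (−2.03 ± 0.14, SE) and MGLL (−2.0 ± 0.29, SE) were lower with E2. All 10 kept their call with each array left out in turn. Estrogen-induced genes were higher with E2 in 12 and lower in 2 of 26 cases, the same over the list alone (median 0.59, adjusted p = 8.24e-07). FOXO targets were higher in 11 of 23 (14 over the list alone; median 0.85, adjusted p = 3.5e-12). Cell cycle brakes were higher in 8 and lower in 1 of 18 (the same over the list alone; median 0.12, 0.25 without E2 replicate 1 and 0.06 without E2 replicate 2, adjusted p = 0.000649) and estrogen-lowered genes were higher in 5 of 12 (6 and 2 lower over the list alone; median 0.22, adjusted p = 0.000402).

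Sterol genes were lower with E2 than with IGF-I at 3 hr in 11 of 14 cases, the same over the list alone (median −0.93, adjusted p = 3.5e-12), and fatty acid genes in 7 of 9, the same over the list alone (median −0.78, adjusted p = 3e-06). G1/S genes were lower in 18 of 34 (27 over the list alone; median −0.42, adjusted p = 1.09e-12) and ribosome biogenesis genes in 10 of 19 (11 over the list alone; median −0.52, adjusted p = 8.24e-07). With an estimated correlation these 4 lists, both estrogen lists, FOXO targets and brakes had adjusted p-values from 0.000184 (sterol) to 0.00945. Immediate early genes (2 higher, 8 lower; median −0.34, adjusted p = 0.00132), amino acid response genes (4 lower; median −0.57, adjusted p = 1.66e-05), glycolysis genes (2 higher, 8 lower; median −0.23, adjusted p = 0.00547) and mitotic genes (6 higher; median 0.18, adjusted p = 0.000485) were also called. Adjusted over the list alone their counts were 2 and 11, 0 and 7, 2 and 9, and 9 and 0. In the same order, their adjusted p-values with an estimated correlation were 0.0587, 0.325, 0.0648 and 0.325. Post hoc, without E2 24 hr replicate 3, 17 amino acid response genes were lower. That list and immediate early genes then passed with an estimated correlation (adjusted p = 0.000479 and 0.0158). Without the dimmer 50% of genes the calls of immediate early, glycolysis and ribosomal protein genes were lost (0.079, 0.0605 and 0.106). Cytosolic ribosomal proteins had 1 higher gene of 16 (0 over the list alone; median 0.07, adjusted p = 0.00642; adjusted p = 0.0266 with an estimated correlation), a call lost when arrays were centred on their medians (adjusted p = 0.0636).

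At 24 hr 1198 genes differed between E2 and IGF-I (592 higher with E2, 606 lower). CAV1 (3.71 ± 0.27, SE), OLFML3 (3.69 ± 0.26, SE), COL21A1, a collagen (3.16 ± 0.18, SE, adjusted p = 1.84e-06), IL17RB, the interleukin-25 receptor (2.91 ± 0.17, SE), and NPY5R, a neuropeptide Y receptor (2.82 ± 0.20, SE), were higher with E2. MME (−2.94 ± 0.25, SE), CLGN (−2.47 ± 0.53, SE), AGTR1, the angiotensin receptor (−2.24 ± 0.33, SE), PCDH8 (−2.17 ± 0.27, SE) and EFNB2 (−2.13 ± 0.21, SE) were lower. CLGN lost its call without E2 replicate 1 (adjusted p = 0.0501). Estrogen-induced genes were higher in 11 of 26 (12 over the list alone; median 0.43, adjusted p = 3.33e-06; adjusted p = 0.0466 with an estimated correlation, and 0.0623 without E2 replicate 3). Fatty acid genes were lower in 5 of 9 (6 over the list alone; median −0.46, adjusted p = 2.06e-05; adjusted p = 0.0262 with an estimated correlation). The count of 1198 was 769 without E2 replicate 1, 763 without IGF-I replicate 3 and 149 with only the 2 groups in the fit (98 higher, 51 lower).

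Mitotic genes were lower with E2 than with IGF-I at 24 hr in 12 of 30 cases (20 over the list alone; median −0.52, adjusted p = 4.59e-12; adjusted p = 0.112 with an estimated correlation). G1/S genes were lower in 4 of 34 (8 over the list alone; median −0.26, adjusted p = 0.000691; adjusted p = 0.112 with an estimated correlation). Amino acid response genes were lower in 12 of 24 (21 over the list alone; median −0.99, adjusted p = 4.83e-12; adjusted p = 0.153 with an estimated correlation). Without E2 replicate 3, 22 of the amino acid response genes (median −1.36) and 20 of the mitotic genes were lower, and both lists passed with an estimated correlation (adjusted p = 2.06e-05 and 0.027). Immediate early genes had 3 higher and 7 lower (3 and 10 over the list alone; median −0.20, adjusted p = 0.00355; adjusted p = 0.112 with an estimated correlation, and median −0.39 and 0.0333 without E2 replicate 3). Ribosomal proteins had 0 called genes, also over the list alone, and a median of 0.12 (adjusted p = 0.00819; adjusted p = 0.0641 with an estimated correlation), and with quantile normalization again the list missed the threshold (0.0659). Glycolysis genes had 1 higher and 3 lower (3 and 8 over the list alone; median −0.26, adjusted p = 0.0111; adjusted p = 0.117 with an estimated correlation), a call lost without E2 replicate 3 (0.0882). Without the dimmer 50% of genes the calls of immediate early genes, ribosomal proteins and glycolysis genes were lost (0.0795, 0.0606 and 0.0936).

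The E2 effect differed between 24 hr and 3 hr in 9 genes (7 more positive and 2 more negative at 24 hr; 782 at an unadjusted p under 0.05). The effect on MME was lower at 24 hr by 3.27 on the log2 scale (−3.27 ± 0.37, SE, adjusted p = 0.00561) and that on APOBEC3G, a cytidine deaminase, by 0.88 (−0.88 ± 0.05, SE, adjusted p = 2.73e-06). The size for MME is uncertain because its E2 level at 24 hr lies near the low band. The 5 largest positive differences were in KIF20A (1.29 ± 0.19, SE, adjusted p = 0.033), TPX2 (1.22 ± 0.20, SE, adjusted p = 0.0496), PRC1 (1.11 ± 0.17, SE, adjusted p = 0.033), RRM2 (1.02 ± 0.13, SE, adjusted p = 0.0159) and ZWINT (0.94 ± 0.14, SE, adjusted p = 0.033), all genes of mitosis or DNA synthesis. All but MME and APOBEC3G lost their call when arrays were left out. TPX2 and PRC1 lost it without any array but those of E2 at 24 hr, and KIF20A and ZWINT without SFM 3 hr replicate 1, any E2 array at 3 hr, or SFM 24 hr replicate 1 or 3. RRM2 lost it without E2 3 hr replicate 1 or SFM 24 hr replicate 3 (adjusted p up to 0.136 over these genes). With the replicate block KIF20A and TPX2 had adjusted p = 0.07. The count became 23 or 17 without SFM 3 hr replicate 1 or 2, and 2, 5 or 4 without E2 3 hr replicate 1, 2 or 3. It was 3 without SFM 24 hr replicate 3 and 49, 18 or 18 without E2 24 hr replicate 1, 2 or 3. The majority turned to negative effects without E2 3 hr replicate 1 or 3 or SFM 24 hr replicate 1 (2 positive, 7 negative) or 3.

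Mitotic genes had a larger E2 effect at 24 hr than at 3 hr (3 of 30 called, 28 over the list alone; median 0.99, adjusted p = 5.67e-50), as did G1/S genes (2 of 34 called, 6 over the list alone; median 0.26, adjusted p = 3.28e-09). Ribosome biogenesis genes had a smaller one (0 of 19 called, 3 over the list alone; median −0.40, adjusted p = 3.73e-09). Mitotic genes did not rise within E2 cells between the times: their median fell by 0.164 there and by 1.17 in SFM. Estimated correlations gave these 3 lists adjusted p-values of 0.00647, 0.0113 and 0.0113. Sterol genes (median 0.28, adjusted p = 0.017; adjusted p = 0.0482 with an estimated correlation), estrogen-lowered genes (−0.21, adjusted p = 0.0234), FOXO targets (−0.25, adjusted p = 0.0199), luminal genes (−0.13, adjusted p = 0.0234) and amino acid response genes (0.28, adjusted p = 0.0234) had 0 called members. Adjusted over the list alone, 1 luminal gene had a more negative effect and the others had 0 called. The last 4 of these lists had adjusted p-values of 0.0758, 0.274, 0.301 and 0.688 with an estimated correlation. All 5 calls depended on single arrays. They were lost without SFM 3 hr replicate 1 (estrogen-lowered and FOXO), SFM 3 hr replicate 2 (sterol, luminal and amino acid response), E2 3 hr replicate 2 (estrogen-lowered), SFM 24 hr replicate 1 (all but FOXO), SFM 24 hr replicate 3 (FOXO), E2 24 hr replicate 1 (sterol, estrogen-lowered and luminal) or E2 24 hr replicate 3 (luminal), with adjusted p-values up to 0.226. Without E2 24 hr replicate 3 the amino acid response list turned to −0.15 with 0 genes called (adjusted p = 0.0319; adjusted p = 0.151 with an estimated correlation). Estrogen-lowered and sterol genes lost their call without the dimmer 50% of genes (adjusted p = 0.0784 and 0.0561), and estrogen-lowered, FOXO and luminal genes with the mean of a gene's probe sets (0.396, 0.195 and 0.135).

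The IGF-I effect differed between the times in 671 genes (313 more positive and 358 more negative at 24 hr). CENPE, a kinetochore motor (2.90 ± 0.36, SE), CDC25C, a phosphatase that starts mitosis (2.71 ± 0.27, SE), NDC80, a kinetochore protein (2.62 ± 0.31, SE), ABCA12 (2.55 ± 0.53, SE) and ZNF750 (2.48 ± 0.35, SE) had the largest positive differences. KCTD12 (−3.36 ± 0.66, SE), OLFML3 (−2.88 ± 0.40, SE), MAFF, a small MAF factor (−2.44 ± 0.26, SE), CAV1 (−2.29 ± 0.41, SE) and PAPSS2 (−2.22 ± 0.44, SE) had the largest negative ones. ABCA12 and PAPSS2 lost their call without SFM 3 hr replicate 1 (adjusted p = 0.0664 and 0.0549) and KCTD12 without SFM 3 hr replicate 2 (0.055). The PGR effect, a fall at 3 hr, was more positive at 24 hr by 1.49. The count of 671 was 357 without SFM 3 hr replicate 1 and 411 without SFM 3 hr replicate 2.

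The IGF-I effect on mitotic genes was more positive at 24 hr in 27 of 30 cases (29 over the list alone; median 1.84, adjusted p = 1.8e-47). On ribosome biogenesis genes it was more negative in 11 of 19 (13 over the list alone; median −0.76, adjusted p = 3.45e-12). That on sterol genes was more negative in 6 of 14 (8 over the list alone; median −0.73, adjusted p = 4.41e-06). That on estrogen-lowered genes was more positive in 1 of 12 (5 positive and 1 negative over the list alone; median 0.49, adjusted p = 0.00443). These 4 lists had adjusted p-values of 0.00265 (mitotic, ribosome biogenesis and sterol) and 0.0299 with an estimated correlation. FOXO targets were more positive in 4 of 23 (10 over the list alone; median 0.48, adjusted p = 7.76e-05; adjusted p = 0.0543 with an estimated correlation). Amino acid response genes were called in 0 of 24, also over the list alone (median 0.64, adjusted p = 0.000202; adjusted p = 0.653 with an estimated correlation). In the post hoc fit without E2 24 hr replicate 3, 10 were more positive and the list passed with an estimated correlation (adjusted p = 0.000692). The IGF axis had 1 of 16, the same over the list alone (median 0.25, adjusted p = 0.0114; adjusted p = 0.208 with an estimated correlation), a call lost without IGF-I 3 hr replicate 1 or SFM 24 hr replicate 1 (up to 0.0586), and with a median of 0.16 without IGF-I 3 hr replicate 1 and 0.43 without replicate 2. Of the genes called at either time, 407 rose and 541 fell with IGF-I at both, and 69 had opposite directions. With E2 47 rose and 53 fell at both times and 0 had opposite directions.

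The controls themselves changed between 3 hr and 24 hr, in 394 genes (157 higher and 237 lower at 24 hr). Mitotic genes fell with further time in SFM, from a list mean of 9.29 ± 0.02 (SD, n = 2) to 8.12 ± 0.14 (SD, n = 3), and 28 of 30 passed the test (30 over the list alone; median −1.17, adjusted p = 4.78e-52). CDC25C (−1.93 ± 0.20, SE, adjusted p = 0.000289), CENPE (−1.87 ± 0.27, SE), DEPDC1 (−1.80 ± 0.39, SE, adjusted p = 0.0235), CCNA2, cyclin A2 (−1.68 ± 0.26, SE), and KIF20A (−1.62 ± 0.14, SE) fell most. PDE8B (2.17 ± 0.32, SE), TNS3 (1.68 ± 0.29, SE), OLFML3 (1.59 ± 0.29, SE), FJX1 (1.55 ± 0.26, SE) and TNFRSF21, a death receptor (1.48 ± 0.09, SE, adjusted p = 6.28e-06), rose most. TNS3 lost its call without either SFM array at 3 hr, OLFML3 without SFM 3 hr replicate 2, FJX1 without SFM 3 hr replicate 1 and DEPDC1 without any array but SFM 24 hr replicate 2 (adjusted p up to 0.201). With array weights 1283 were higher and 1170 lower. The count was 165 (37 higher, 128 lower) and 200 without SFM 3 hr replicates 1 and 2, and 247 and 232 without SFM 24 hr replicates 2 and 3.

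Also over time in SFM, ribosome biogenesis genes rose in 7 of 19 cases (13 over the list alone; median 0.57, adjusted p = 8.61e-12). Immediate early genes rose in 4 of 22 (9 over the list alone; median 0.29, adjusted p = 7.04e-06). G1/S genes fell in 6 of 34 (10 over the list alone; median −0.30, adjusted p = 4.78e-10), and sterol genes in 2 of 14, the same over the list alone (median −0.22, adjusted p = 0.000211). Fatty acid genes fell in 1 of 9 (2 over the list alone; median −0.30, adjusted p = 0.00208). With an estimated correlation mitotic and ribosome biogenesis genes had an adjusted p of 0.00382, immediate early genes 0.0176, G1/S and sterol genes 0.00656 and fatty acid genes 0.0294. Amino acid response genes (median 0.35, adjusted p = 0.035; adjusted p = 0.734 with an estimated correlation) and interferon-stimulated genes (median −0.13, adjusted p = 0.0301; adjusted p = 0.25 with an estimated correlation) had 0 called members, also over the list alone. Fatty acid genes lost their call without SFM 3 hr replicate 2, interferon genes without SFM 3 hr replicate 2 or SFM 24 hr replicate 1, and amino acid response genes without any array but SFM 24 hr replicate 2 (adjusted p up to 0.0953). With E2 24 hr replicate 3 left out post hoc, 4 amino acid response genes rose and 1 fell. The list passed with an estimated correlation (adjusted p = 0.0129). The interferon call was lost without the dimmer 50% of genes (adjusted p = 0.187).

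Apoptosis regulators, interferon-stimulated genes and the markers of other cell types passed no test against SFM. Apoptosis regulators had adjusted p-values of 0.851 and 0.677 (E2 and IGF-I at 3 hr) and 0.564 and 0.88 (24 hr), although BIK fell and TNFRSF21 (1.52 ± 0.09, SE, IGF-I at 3 hr) rose. BCL2, a survival gene, fell with IGF-I by 1.09 ± 0.14 at 3 hr and by 1.16 ± 0.12 (SE) at 24 hr. Interferon-stimulated genes had adjusted p-values of 0.605, 0.797, 0.853 and 0.564 in the same order, and 3 of 20 rose and 1 fell with IGF-I at 24 hr. Markers of basal, mesenchymal, endothelial and blood cells had 0.719, 0.801, 0.869 and 0.417, and VIM, vimentin, fell with IGF-I at 24 hr (−0.83 ± 0.20, SE). Estrogen-induced genes had 5 rises and 4 falls with IGF-I at 3 hr (adjusted p = 0.348) and 4 rises and 3 falls at 24 hr (adjusted p = 0.0724, and 0.0259 without IGF-I replicate 1). Cell cycle brakes at 24 hr of IGF-I had 2 rises, among them CDKN1A, the gene of p21 (1.16 ± 0.17, SE), and 7 falls (adjusted p = 0.0699). The brakes passed with quantile normalization again (0.0333), with median centring (0.0322), without the dimmer 50% of genes (0.00741) and without SFM replicate 1, IGF-I replicate 3 or E2 replicate 3 (0.0453, 0.0283 and 0.0401). Endoplasmic reticulum chaperones had adjusted p-values of 0.0755 at 3 hr and 0.0732 at 24 hr of IGF-I, and passed at 3 hr with the mean of a gene's probe sets (0.0357) and at 24 hr without SFM replicate 3 or IGF-I replicate 1 (0.0468 and 0.0412). The IGF axis had adjusted p-values of 0.0982 and 0.0913 with E2 at 3 and 24 hr and 0.962 with IGF-I at 24 hr. With E2 it passed without SFM replicate 1 or E2 replicate 3 at either time (0.0217 at 24 hr without E2 replicate 3). Median, mean and test of a list differed in sign only for lists that did not pass, among them basal markers with IGF-I at 3 hr and with E2 at 24 hr, immediate early and interferon genes with E2 at 24 hr, and the IGF axis, apoptosis and interferon lists with IGF-I at 24 hr.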

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

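The tests of the amino acid response genes in 1 array, both tests of the mitotic genes, the fits without E2 24 hr replicate 3 in comparisons that do not hold it, the ACTB covariate, and the replicate block with the 3 hr arrays alone were chosen only after the result was seen.

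Singled out here were effects that differed between 3 and 24 hr by the interaction test, and signals in probe sets without a single gene name. For E2 the interaction was called in 9 genes, and among the genes named in the report it was KIF20A (1.29), TPX2 (1.22), PRC1 (1.11), RRM2 (1.02), ZWINT (0.94), TYMS (0.80), MME (−3.27) and APOBEC3G (−0.88). The lists whose E2 effect differed were mitotic genes (median 0.99), G1/S genes (0.26), sterol genes (0.28), amino acid response genes (0.28), ribosome biogenesis (−0.40), FOXO targets (−0.25), estrogen-lowered genes (−0.21) and luminal genes (−0.13). Calls lost with an estimated correlation were amino acid response (adjusted p = 0.688), FOXO (0.274), estrogen-lowered (0.0758) and luminal (0.301). Without E2 24 hr replicate 3 the amino acid response median was −0.148.

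For IGF-I the interaction was called in 671 genes. It includes SFM changes over time, as in TNFRSF21 (1.48), PDE8B (2.17) and ribosome biogenesis (median 0.57), weighed only for mitotic genes. More positive at 24 hr among named cell division genes were CENPE (2.90), CDC25C (2.71), NDC80 (2.62), HMMR (2.21), KIF20A (2.14) and PRC1 (1.87). Further ones included CDCA8 (1.65), NUSAP1 (1.56), CDC45 (1.44), CCNB1 (1.35), RRM2 (1.20), CCNB2 (1.14), BUB1B (1.13) and TYMS (0.80). Others included MYBL1 (2.15), FILIP1L (2.13), CA4 (2.09), KMO (2.05), ELF5 (1.94), RASSF1 (1.84), PGR (1.49), TXNIP (1.42), PIK3R3 (1.29), CCDC28A (1.14), SCD (1.03), HBP1 (0.70), ALDOA (0.63) and SEL1L (0.63). More negative at 24 hr were the ribosome biogenesis genes DDX21 (−1.41), NOP16 (−1.35), NOLC1 (−1.28), BYSL (−1.06), WDR43 (−0.62) and NPM1 (−0.35). So were the lipid synthesis genes HMGCS1 (−1.89), MSMO1 (−1.34) and ELOVL6 (−0.74). Further negative differences included KCTD12 (−3.36), OLFML3 (−2.88), MAFF (−2.44), CAV1 (−2.29), PDE8B (−1.78), EGR3 (−1.77), PHLDA2 (−1.61), FHL2 (−1.57), PFKFB3 (−1.56), TUBB2A (−1.49), TNFRSF21 (−1.44), MICAL2 (−1.38), METTL1 (−1.32), STC2 (−1.09), SDF2L1 (−0.81) and XBP1 (−0.50). The lists were mitotic genes (1.84), amino acid response genes (0.64), estrogen-lowered genes (0.49), FOXO targets (0.48), the IGF axis (0.25), sterol genes (−0.73) and ribosome biogenesis (−0.76). An estimated correlation ended the calls of amino acid response (adjusted p = 0.653), FOXO (0.0543) and the IGF axis (0.208).

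Probe sets without a single gene name, 3151 outside the controls, were not used in the gene tests. Of these, 14 and 278 passed the same threshold with E2 and IGF-I at 3 hr, and 70 and 354 at 24 hr.

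Replicate 3 of E2 at 24 hr stood apart most in the amino acid response genes. SLC7A11, the cystine transporter, was at 8.74 there against 5.45 as the mean of replicates 1 and 2, with 8.43 in IGF-I and 5.34 in SFM, and ASNS at 12.43 against 10.05. An IGF-I array under a wrong label is argued against by 39 estradiol-raised genes, whose median position was 0.966 on a scale from the IGF-I level (0) to that of the other E2 arrays (1), and by PGR (8.08), IL17RB (8.52) and OLFML3 (8.72), which were at the E2 level. RNA of IGF-I cells mixed in would need a share of 0.891, which, with a tolerance of 0.25 added, allows a position of at most 0.359 on the linear scale, where 0.921 was found; the ACTB 3' minus 5' signal of 0.7803 lay inside the range of the other 16 arrays (0.479 to 1.52), which argues against RNA quality. A difference in the culture of that replicate, such as its amino acid supply, may explain the pattern and stays open; no biological explanation was tested.

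Mitotic genes had a more positive IGF-I effect at 24 hr than at 3 hr by a median of 1.84. A fall of the controls alone is argued against, since between the times the list also rose within IGF-I cells by 0.622 (SE 0.0535 of the list mean) while it fell by 1.17 in SFM and by 0.164 in E2 cells. List means were 9.29, 9.16 and 8.91 at 3 hr and 8.12, 8.97 and 9.45 at 24 hr in SFM, E2 and IGF-I. With the ACTB covariate 28 of the 30 genes had a called interaction. This leaves RNA quality open, as ACTB differed alike at 3 and 24 hr (IGF-I minus SFM −0.139 and −0.16). It stays open whether starved cells left the cycle over 24 hr while IGF-I cells went from DNA synthesis to mitosis. Cell cycle phase was not measured, so this was not tested.

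Same-numbered E2 and IGF-I arrays at 3 hr deviated together from their group means, with correlations across genes of 0.561, 0.26 and 0.49. After the trend with the ACTB 3' minus 5' signal was removed they were 0.261, 0.231 and 0.448, so RNA quality as the whole cause is argued against (lowest remaining value 0.231). A shared day, plating or hybridisation of same-numbered arrays could explain it and stays open, since the labels name none. With the 3 hr arrays alone and the number as a block, a fit added later, 2240 genes differed between E2 and IGF-I at 3 hr.

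Regroupings of the arrays were also counted. For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real split gave 665 calls for E2 against SFM at 24 hr (highest other split 26), 2542 for IGF-I against SFM at 24 hr (highest other 1), 1657 for E2 against IGF-I at 3 hr (highest other 2) and 1198 for E2 against IGF-I at 24 hr (highest other 63), and in each of these comparisons 1 split, the real one, reached the real count. For E2 against IGF-I at 3 hr, where the numbers may pair the arrays, the other splits that part all 3 pairs called 0 genes and those that part fewer called at most 2. For genes called with both agents at 24 hr, 2 of 100 drawn splits reached the real 468. The other had the IGF-I arrays as controls (785), so the count does not single out a shared effect. With E2 arrays as controls it was 34, and mixed splits gave at most 11.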

How the results depend on the processing

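Leaving out E2 24 hr replicate 3 everywhere, the ACTB covariate and the 3 hr-only block were post hoc. Of 207 recomputed counts of calls, 160 stayed within 1.5 times the reported count and 47 did not. Of 6073 recomputed gene results 5572 kept their direction and side of the threshold, 416 lost and 75 gained a call and 10 reversed; of 2299 recomputed list results 2137 were the same, 127 lost and 33 gained a call and 2 reversed. Quantile normalization again, the mean of a gene's probe sets, every probe set on its own, the trended robust prior and the ACTB covariate left every count within 1.5 times.

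With array weights the counts were 478 (E2, 3 hr), 3023 and 4471 (IGF-I, 3 and 24 hr), 65 and 2010 (E2 and IGF-I effects over time), 2453 (SFM over time) and 313 (both agents, 3 hr); SFM 24 hr replicate 3 had a weight of 7.67. With only the arrays of the groups compared they were 53 and 84 (E2, 3 and 24 hr), 149 (E2 against IGF-I, 24 hr), 2 and 1014 (E2 and IGF-I effects over time) and 212 (both agents, 24 hr), with fewer arrays to estimate the spread. At a minimum fold of 1.5, which removes smaller changes by construction, they were 1537 (IGF-I, 24 hr), 983 and 661 (E2 against IGF-I, 3 and 24 hr) and 304 (both agents, 24 hr). The E2 effect over time had 4 calls with median centring and 14 without the dimmer 50% of genes. Without E2 24 hr replicate 3 anywhere, calls numbered 265 (E2, 3 hr, with all 152) and 158 (both agents, 3 hr). They numbered 2239 and 2799 (IGF-I, 3 and 24 hr), 946 (IGF-I effect over time) and 542 (SFM over time). Median centring gave 40.2% higher with E2 than with IGF-I at 3 hr (717 higher, 1065 lower) against 51% as deposited. For the E2 effect over time it gave 50% against 77.8%. With IGF-I at 3 hr it gave 1106 higher and 827 lower against 953 and 987, so the majority of falls turned. The cause was not tested.

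Leaving out single arrays of a comparison gave 83 to 117 and 1111 to 1703 calls (E2 and IGF-I, 3 hr). At 24 hr it gave 395 to 972 and 1917 to 2247. E2 against IGF-I had 1193 to 1431 and 763 to 1561 (3 and 24 hr). The E2 and IGF-I effects over time had 2 to 49 and 357 to 600, and SFM over time 165 to 309. Both agents shared 57 to 79 and 288 to 690 (3 and 24 hr).

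Reversals came mostly from a gene's next, dimmer probe set: IL1R1 (0.000296 with E2 and 0.0504 with IGF-I, 3 hr), ESR1 (0.0716 with E2 and 0.0321 with IGF-I, 24 hr), KMO (0.0585) and ERBB3 (0.0681, both IGF-I, 3 hr), INSR (0.0118, E2, 24 hr), TYMS (−0.105 with E2 and −0.0235 with IGF-I, 24 hr) and BCL2 (0.0171, IGF-I, 24 hr). The means of the reported and next probe sets were 4.19 and 3.13 (IL1R1), 11.8 and 7.64 (ESR1), 9.9 and 3.38 (ERBB3) and 10.9 and 2.86 (TYMS); the cause was not tested. In the E2 effect over time the basal marker list was at 0.581 without the dimmer 50% of genes, where most of its members are absent, and the amino acid response list ran from −0.148 (without E2 24 hr replicate 3) to 0.526 (without replicate 2) with single arrays left out.

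The replicate block gave 121, 1763, 624 and 2556 calls (E2 and IGF-I at 3 hr, E2 and IGF-I at 24 hr), 1646 and 1155 (E2 against IGF-I, 3 and 24 hr), 11 and 638 (E2 and IGF-I effects over time), 305 (SFM over time), and 74 and 443 (both agents). It ended the calls of MYC, ERBB2, SLC7A11 (0.0971) and SELENOP (0.0668) with IGF-I at 3 hr, METTL1 and PMAIP1 with E2 at 3 hr, MNS1, ETV4, INSR and MSMO1 with E2 at 24 hr, NOLC1 with IGF-I at 24 hr, KIF20A and TPX2 in the E2 effect over time and DEPDC1 in SFM, and of 2 lists, immediate early genes with E2 at 3 hr (0.0559) and the amino acid response in SFM (0.188). It added IGFBP5 and KLF4 with E2 and the brakes in the IGF-I effect over time, and changed no other call of a named gene or list. The numbers may pair arrays for E2 against IGF-I at 3 hr, where no call of a named gene or list changed. Signal near the low band limits what can be seen of dim genes.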

Other observations

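The counts of genes with opposite directions and the look within E2 24 hr were chosen after the values were seen, and the genes named were picked for their direction. A small set of genes moved in opposite directions with the agents. At 3 hr 11 genes rose with E2 and fell with IGF-I and 1 did the reverse, where independent lists would give 12.3 in all. Among the 11 were PGR (1.13 with E2, −1.36 with IGF-I), the neuropeptide Y receptors NPY5R (1.20 and −1.10) and NPY1R (0.67 and −0.49), and DEPTOR, an inhibitor of mTOR (0.86 and −1.81). MMD was the reverse case (−0.65 and 0.77). At 24 hr 17 genes rose with E2 and fell with IGF-I and 10 did the reverse, against 70.3 for independent lists. COL21A1 (1.84 and −1.32), OLFML3 (1.33 and −2.36), IL17RB (1.80 and −1.11), ABHD2 (1.23 and −1.34), NPY5R (0.97 and −1.85), NPY1R (0.50 and −1.46) and DEPTOR (0.52 and −0.83) were in the first group. TOX3 (−0.68 and 1.38), EFNB2, an ephrin ligand (−1.35 and 0.78), IER3 (−1.10 and 0.66) and TGFB3, a growth factor (−0.57 and 0.67), were in the second.

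Within the E2 24 hr group, genes outside the amino acid response also stood apart in replicate 3. DIO1, a thyroid hormone deiodinase, was at 6.28 there against 3.68 as the mean of replicates 1 and 2 and PLAT at 6.15 against 3.64. In IGF-I cells at 24 hr these genes were at 2.16 and 3.32.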
